A study of Homo sapiens with 9 samples.

How the data were processed

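The deposited files hold, for each library, a normalised read count per gene, a score that the authors obtained by scaling each library's reads and rounding to whole numbers. The submitters' notes name STAR, featureCounts, Subread and edgeR with no version given, and hg19 as the genome build. Each file lists 60420 gene IDs, of which 45742 stand at 0 in all 9 libraries. The authors' filter appears to have been applied once to the EV control and construct 86 libraries together, whose values give the EV files, and once to the EV control and construct 87 libraries together. The signs are that 400 IDs are above 0 only in the EV and construct 86 files and 453 only in the construct 87 files, and that 0 of the 400 reach 14 in all 3 EV libraries while 264 of the 453 do so in fewer than 3 construct 87 libraries. A value of 0 across a whole group therefore means filtered, not unexpressed. The 13825 gene IDs above 0 in both sets were tested.

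Because the values are whole multiples of a constant per library before rounding, that constant was recovered from the spacing of the values and the reads behind each value were recovered with it. The libraries were then rescaled together with the TMM formula (trimming 30% of the log ratios and 5% of the abundances). This was done because the construct 87 files appear to have been normalised separately. Levels are given as normalised reads on that common scale. A test on counts had been planned, but as the values are scaled and rounded the test used was limma (version 3.58.1 in R 4.3.3) on log2 of the value plus 1, with a variance trend, 1 coefficient for each of the 3 groups and 6 residual degrees of freedom. Its p-values are two-sided and adjusted by Benjamini-Hochberg over the 13825 genes, with a threshold of 0.05 and no fold minimum. Fold changes are on the log2 scale of the value plus 1, which understates those of genes with few reads. In 10 simulations with 200 genes changed between construct 86 and EV libraries, the test recovered 27.7% of 2-fold and 78.9% of 4-fold changes, with 5.2 false calls on average. The simulated libraries varied independently, with no trend by transcript length and no pairing by replicate number. In the real data far more genes passed (4925 with construct 86). These rates may therefore not hold for the real libraries.

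Altogether 38 gene lists were fixed before the data were examined, as were the comparisons, most of the other settings and the rule for named genes. A list with at least 3 tested members was tested with camera in limma, two-sided, with a preset inter-gene correlation of 0.01, adjusted over the 37 lists and both constructs, and again with an estimated correlation. All calls of lists at the preset correlation were lost with the estimated correlation. The rule names the SPANX genes, LMNA, LMNB1, LMNB2, EMD, CDKN1A, MKI67, CCND1 and MITF in every case. It adds the 12 rises and 12 falls shared by both constructs with the largest smaller change, among genes of a mean of at least 5 CPM (reads scaled to a common library size) whose knockdown libraries all lie beyond all EV libraries. It then adds the 6 largest rises and 6 largest falls of each construct among genes whose change also differed between constructs. Last come up to 4 members of each list described, those with the smallest adjusted p for the mean of both constructs, and genes without a standard symbol or with near-identical copies could be passed over.

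The replicate numbers were checked for pairing. Over 12353 genes, deviations from the group mean correlated with r between 0.186 and 0.78 across genes for the 9 pairs of libraries of the same number in different groups, and between -0.693 and 0.199 for all other such pairs. In 8 of 9 libraries the best partner within each of the other groups carried the same number. The exception was EV replicate 1, with r = 0.199 to construct 87 replicate 3 and 0.186 to construct 87 replicate 1. Counts from a model with the replicate number as a block are therefore given beside the main counts. Transcript lengths came from the GENCODE v29 basic annotation. The length correction removed, from each library, a spline with 4 degrees of freedom in log length. In 100 simulations all 9 libraries, EV included, were drawn unchanged from each gene's mean and spread. They show what a shared control alone produces where libraries vary independently. The length trend and the pairing by replicate number were not simulated. The sum of the SPANX genes was compared by an exact two-sided permutation test, which with 3 libraries against 3 cannot go below p = 0.1. Nothing in the labels says that the replicates come from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.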

Results

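The transcripts of A375 cells, a human melanoma cell line, were counted from their 3' ends (QuantSeq 3' mRNA-Seq) 7 days after knockdown of SPANX, a family of cancer-testis antigens normally made in sperm cells. The 9 libraries fall into 3 groups of 3: an EV control and knockdown by construct 86 or construct 87. The recovered depth was 12.87, 14.55 and 12.32 M reads in the EV libraries, 14.41, 15.56 and 11.31 M with construct 86, and 12.67, 15.27 and 12.75 M with construct 87. Replicates of a group correlated across genes with r between 0.921 and 0.963 for EV, 0.956 and 0.975 for construct 86 and 0.953 and 0.976 for construct 87. The first principal component held 49.6% of the variance and ordered the groups as EV, construct 87 and construct 86, except that EV replicate 2 lay at -20.49, above construct 87 replicate 3 at -31.09.

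The targeted transcripts fell with both constructs. Of 10 SPANX genes in the files, 2 had values above 0. SPANXC (ENSG00000198573.6) stood at 354 ± 185 normalised reads in EV libraries, 59.7 ± 36.6 with construct 86 and 25.6 ± 7.8 with construct 87 (SD, n = 3 each). Its level was 400, 149.8 and 510.9 in the EV libraries, 101.7, 35.14 and 42.21 with construct 86, and 25.22, 17.98 and 33.6 with construct 87, so every knockdown library lay below every EV library. The limma test gave a log2 fold change of -2.53 with construct 86, which is 5.78-fold lower (adjusted p = 0.00372), and of -3.60 with construct 87, which is 12.2-fold lower (adjusted p = 0.00334). The difference between the constructs did not pass the threshold (adjusted p = 0.149), but did with the replicate block (adjusted p = 0.0221). SPANXD (ENSG00000196406.4) stood at 102.2, 27.4 and 97.01 in the EV libraries, at 0.9686, 0.8784 and 0 with construct 86, and at 5.255, 5.994 and 7.127 with construct 87 (adjusted p = 1.45e-04 and 0.00804). With construct 86 it rested on 2 reads against 212 in EV libraries, a ratio of 110 (exact 95% Clopper-Pearson interval 30 to 912, counting error only). With construct 87 it was 9.32-fold lower by limma. That fold is on the scale of the value plus 1, not a ratio of reads, so it cannot be set against the ratio of 110. The sum of both genes was 7.12-fold lower with construct 86 and 13.5-fold lower with construct 87, each with exact permutation p = 0.1, the smallest possible. Leaving out 1 library moved its log2 ratio from -2.83 to between -3.46 and -2.49 with construct 86. With construct 87 it moved from -3.76 to between -4.13 and -3.42. SPANX copies are nearly identical in sequence, so the share of each member is uncertain, and the files give no coordinates.

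**Figure D1:**
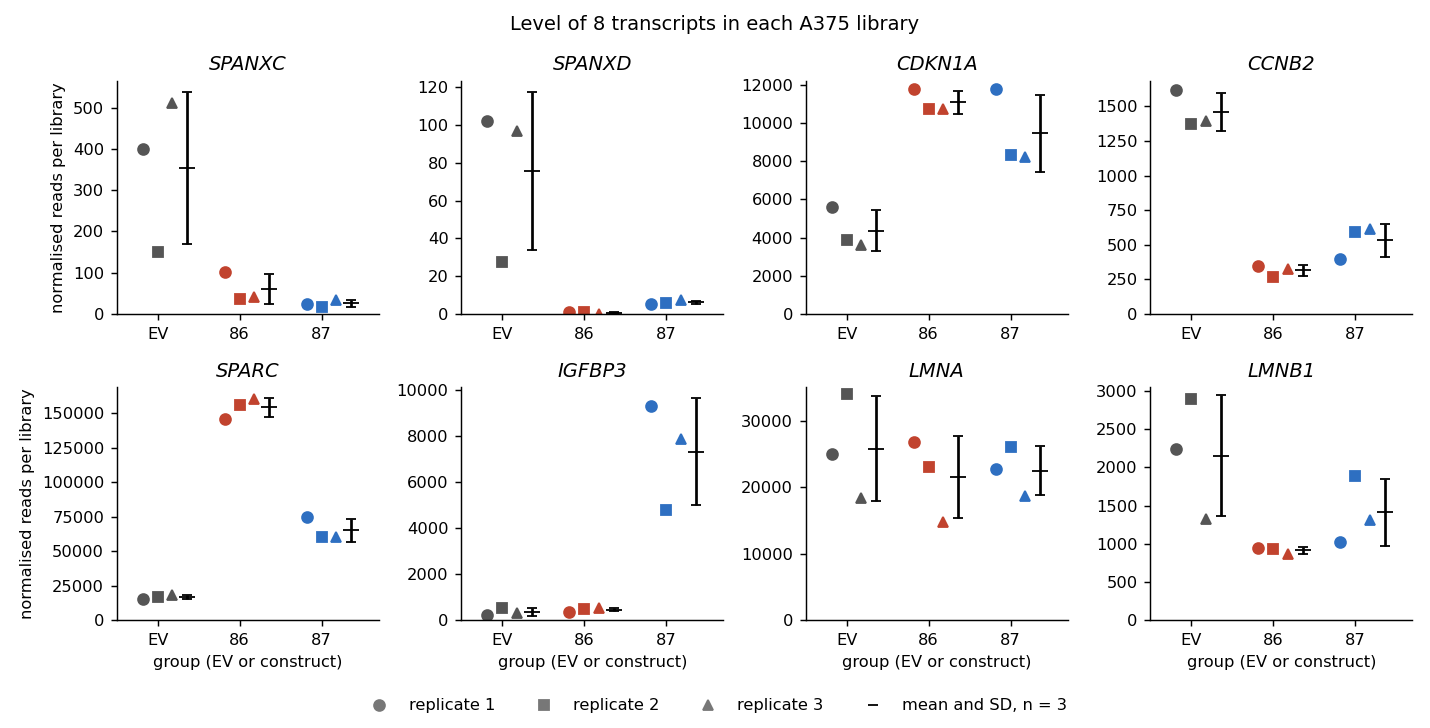
Normalised reads (vertical axis, starting at 0) of 8 transcripts in each A375 library, by group (EV, construct 86, construct 87), with 1 marker shape per replicate number and the mean and SD of 3 libraries as a black bar. SPANXC and SPANXD lie lower in all knockdown libraries than in any EV library, IGFBP3 lies high with construct 87, and LMNA overlaps between the groups.

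The study's title concerns Lamin A/C and nuclear architecture, and the transcripts of the nuclear lamina were compared for that reason. LMNA (ENSG00000160789.19), which encodes lamins A and C, stood at 25781 ± 7887 in EV libraries, 21567 ± 6103 with construct 86 and 22498 ± 3709 with construct 87 (SD, n = 3 each), with log2 fold changes of -0.26 (adjusted p = 0.534) and -0.16 (adjusted p = 0.76). LMNB1, which encodes lamin B1 and whose loss is a mark of senescence, fell 2.24-fold with construct 86 (adjusted p = 0.0125) and had a log2 fold change of -0.58 with construct 87 (adjusted p = 0.234), and the difference between constructs gave an adjusted p of 0.18. LMNB2 had log2 fold changes of -0.71 (adjusted p = 0.138) and -0.67 (adjusted p = 0.25). EMD, which encodes emerin of the inner nuclear membrane, had log2 fold changes of -0.24 (adjusted p = 0.335) and 0.45 (adjusted p = 0.159), and here the difference between constructs passed (adjusted p = 0.0226; 0.0856 with the length trend removed). LBR, a receptor that ties the lamina to chromatin, fell 1.92-fold with construct 86 (adjusted p = 0.00223). Of 23 tested members of the nuclear lamina and envelope list, 5 rose and 3 fell with construct 86, while 0 rose and 1 fell with construct 87; adjusted over the list alone, 6 rose and 3 fell, and 0 rose and 1 fell. The camera test of the list gave adjusted p = 0.46 with construct 86 and 0.04, downward, with construct 87. The latter call was lost without EV replicate 2 (adjusted p = 0.262), without construct 87 replicate 3 (adjusted p = 0.231), without a variance trend (adjusted p = 0.0532), with fry (adjusted p = 0.223) and with an estimated correlation (adjusted p = 0.6 with an estimated correlation). Among the growth genes named beforehand, MKI67, a marker of cycling cells, had log2 fold changes of -0.26 (adjusted p = 0.78) and -1.20 (adjusted p = 0.263). CCND1, which encodes cyclin D1, rose 3.15-fold with construct 86 (adjusted p = 0.00218) and had a log2 fold change of 0.86 with construct 87 (adjusted p = 0.0921). MITF, the master regulator of melanocytes, had log2 fold changes of -0.11 (adjusted p = 0.78) and 0.33 (adjusted p = 0.451). With the replicate number as a block, MKI67 also passed with construct 87 (adjusted p = 0.00279), as did CCND1 (adjusted p = 0.00832), EMD (adjusted p = 0.0437) and LBR (adjusted p = 0.0347), LMNB2 passed with both constructs (adjusted p = 0.0113 and 0.0282), and LMNB1 differed between the constructs (adjusted p = 0.0484). Over all named genes the block gained 50 calls and lost 0.

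Construct 86 was compared with EV to find the transcripts that changed with this knockdown. Most of the G2/M and mitosis genes tested fell (35 of 52), and most of the matrix and adhesion genes (27 of 36), lysosomal genes (20 of 29) and TGF-beta targets (15 of 23) rose. The camera calls of these lists were lost with adjusted p = 0.44, 0.34, 0.32 and 0.32 with an estimated correlation. SCUBE3, a secreted glycoprotein, rose 265-fold, from 27.4 ± 13.2 in EV libraries to 6946 ± 1680 (SD, n = 3 each; limma adjusted p = 4.62e-06). SPON2, a secreted matrix protein, rose 66.7-fold, from 79.3 ± 21.9 to 5285 ± 991 (adjusted p = 1.27e-05). ACAN, the cartilage proteoglycan aggrecan, rose 102-fold (adjusted p = 6e-05), C10orf10 36.3-fold (adjusted p = 8.8e-05) and FAM180A 41.2-fold (adjusted p = 0.00141). The deepest falls that also differed from construct 87 were those of ALDH3B1, an aldehyde dehydrogenase, which fell 13.2-fold from 741 ± 57.8 to 55.7 ± 7.94 (adjusted p = 6.42e-06), and of HPDL (10-fold), TSPYL4 (9.97-fold), HMMR (9.01-fold), CHML (8.55-fold) and BTG3 (8.53-fold), whose adjusted p ran from 4.32e-05 for HPDL to 0.000321 for BTG3. In all, 2493 genes were higher and 2432 lower of 13825 tested, 35.6%; of these, 1674 and 1486 changed more than 2-fold. With the replicate block 7647 genes passed, and without construct 86 replicate 2 the count was 3075.

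With construct 86, of 52 G2/M and mitosis genes tested 35 fell and 0 rose (39 and 0 adjusted over the list alone), and of 45 G1/S and DNA replication genes 26 fell and 0 rose (27 and 0 adjusted over the list alone). CCNB2 and CCNB1, cyclins of mitotic entry, fell 4.64-fold and 3.47-fold (adjusted p = 9.52e-05 and 0.000523), and MCM6, part of the replicative helicase, fell 2.7-fold (adjusted p = 0.00137). Camera gave adjusted p = 1.9e-10 for G2/M and 8.4e-07 for G1/S; these were adjusted p = 0.44 and adjusted p = 0.48 with an estimated correlation. Of 33 p53 targets, 17 rose and 0 fell (17 and 1 adjusted over the list alone; camera adjusted p = 0.00013, and adjusted p = 0.36 with an estimated correlation). CDKN1A, the CDK inhibitor p21, rose 2.58-fold (adjusted p = 0.00147), the pro-apoptotic BBC3 3.41-fold (adjusted p = 0.000138) and the anti-proliferative BTG2 5.41-fold (adjusted p = 7.5e-05).

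Matrix and adhesion transcripts rose with construct 86 in 27 of 36 tested members, and 1 fell (28 and 2 adjusted over the list alone; camera adjusted p = 9e-10, and adjusted p = 0.34 with an estimated correlation). SPARC, a collagen-binding glycoprotein, went from 16911 ± 1666 to 154160 ± 7165 (9.14-fold, adjusted p = 2.81e-05), and ITGAV, the integrin alpha V chain, rose 6.07-fold (adjusted p = 5.14e-05). Fibroblast markers, which share matrix genes with that list, rose in 8 of 12, and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0036, and adjusted p = 0.32 with an estimated correlation). TGF-beta targets rose in 15 of 23 with 0 falls (15 and 1 adjusted over the list alone; camera adjusted p = 8e-06, and adjusted p = 0.32 with an estimated correlation), among them BAMBI, a pseudoreceptor of the TGF-beta family, 4.54-fold (adjusted p = 7.11e-05). Lysosomal genes rose in 20 of 29 and fell in 2 (20 and 2 adjusted over the list alone; camera adjusted p = 3.7e-06, and adjusted p = 0.32 with an estimated correlation), with the lysosomal protease CTSA up 3.96-fold (adjusted p = 0.000115). Of 23 AKT and FOXO targets 12 rose and 1 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.00026, and adjusted p = 0.2 with an estimated correlation). Of 38 MYC targets and ribosome biogenesis genes 23 fell and 0 rose (26 and 0 adjusted over the list alone; camera adjusted p = 5.3e-07, and adjusted p = 0.43 with an estimated correlation), such as NOP56, a nucleolar protein of box C/D particles, 2.19-fold (adjusted p = 0.00105), and DKC1, the dyskerin pseudouridine synthase, 2.54-fold (adjusted p = 0.00061). Of 23 heat shock genes 13 fell and 0 rose (16 and 0 adjusted over the list alone; camera adjusted p = 0.00012, and adjusted p = 0.45 with an estimated correlation), including the chaperone HSP90AA1, 3.3-fold (adjusted p = 0.000797), and its partner FKBP4, 3.98-fold (adjusted p = 9.27e-05). Short transcripts were scarcer in these libraries, as given with the transcript length trend. Oxidative phosphorylation genes, most of which have short transcripts, fell in 10 of 55 and rose in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 3.1e-06, and adjusted p = 0.54 with an estimated correlation). Their camera adjusted p was 0.0019 with the length trend removed, and 47 of them fell with the replicate block.

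Construct 87 was compared with EV in the same way. Fewer genes passed: 818 were higher and 613 lower of 13825, 10.4%, of which 592 and 410 changed more than 2-fold. IGFBP3, a secreted binder of insulin-like growth factors, rose 20.6-fold, from 362 ± 156 to 7322 ± 2308 (SD, n = 3 each; limma adjusted p = 0.000217), while its log2 fold change with construct 86 was 0.42 (adjusted p = 0.328). KCNS3, a potassium channel subunit, rose 10.6-fold (adjusted p = 0.0023), and PRDM1, the transcriptional repressor BLIMP1, 7.33-fold (adjusted p = 0.000393). GLTP, a glycolipid transfer protein, fell 5.98-fold, from 683 ± 171 to 112 ± 21.6 (adjusted p = 0.000393), and MYBL2, a transcription factor of cell cycle genes, 6.95-fold (adjusted p = 0.00155). AKR1C1 and AKR1C2, reductases of steroids with close copies that can share reads, fell 9.14-fold (adjusted p = 0.000611) and 6.98-fold (adjusted p = 0.00483). ST8SIA4, a polysialyltransferase, fell 6.77-fold (adjusted p = 0.000472). With the replicate block 4284 genes passed. The count was 518 without EV replicate 1, 2556 without EV replicate 2, 378 without construct 87 replicate 1 and 606 without construct 87 replicate 2.

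With construct 87, the lists of cell division genes again passed downward in camera, with adjusted p = 4.7e-21 for G2/M and 1.8e-15 for G1/S, and for each list adjusted p = 0.32 with an estimated correlation. Of 52 G2/M genes 28 fell and 0 rose (47 and 0 adjusted over the list alone), and of 45 G1/S genes 20 fell and 0 rose (33 and 0 adjusted over the list alone). CCNB2 fell 2.78-fold (adjusted p = 0.00364), CCNB1 2.69-fold (adjusted p = 0.00688) and MCM6 3.16-fold (adjusted p = 0.00334). Of 33 p53 targets 14 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 3.4e-06, and adjusted p = 0.32 with an estimated correlation), such as BBC3, 2.62-fold (adjusted p = 0.00272), and TP53INP1, an autophagy and stress protein, 3.5-fold (adjusted p = 0.0026). CDKN1A rose 2.17-fold (adjusted p = 0.0135), a call lost without construct 87 replicate 1 (adjusted p = 0.0722). Of 10 replication-dependent histone genes 8 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 3.1e-06, and adjusted p = 0.32 with an estimated correlation), with HIST1H4H up 7.22-fold (adjusted p = 0.00223) and HIST1H2BD 3.88-fold (adjusted p = 0.00638); histone genes have close copies, and single members are uncertain. Matrix and adhesion genes rose in 9 of 36 and fell in 1 (14 and 3 adjusted over the list alone; camera adjusted p = 0.00029, and adjusted p = 0.49 with an estimated correlation), with SPARC up 3.85-fold (adjusted p = 0.00161) and ITGAV 2.76-fold (adjusted p = 0.00334). Lysosomal genes rose in 8 of 29 and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.00019, and adjusted p = 0.34 with an estimated correlation), with MANBA, a lysosomal mannosidase, up 3.18-fold (adjusted p = 0.00411). Of 23 AKT and FOXO targets 7 rose and 0 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00029, and adjusted p = 0.2 with an estimated correlation). Among 38 MYC targets and ribosome biogenesis genes 4 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 3.4e-06, and adjusted p = 0.45 with an estimated correlation).

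The overlap of the constructs asks which changes do not depend on a single construct. TRAF1, an adaptor of TNF receptors, rose 19.9-fold with construct 86 and 12.4-fold with construct 87, from 64.0 ± 12.7 in EV libraries to 1380 ± 582 and 799 ± 120 (SD, n = 3 each; limma adjusted p = 4.32e-05 and 0.000472). CITED1, a melanocyte transcriptional coactivator, rose 22-fold and 12.1-fold (adjusted p = 2.77e-05 and 0.000393), and KDR, a receptor of VEGF, 15.3-fold and 8.54-fold (adjusted p = 0.000453 and 0.0065). MOBP, a myelin protein, stood at 0.370 ± 0.642 in EV libraries, where it rested on 1 read, and at 193 ± 81.9 and 344 ± 222 with the constructs (adjusted p = 2.77e-05 and 0.000109). Other shared rises were those of ABCB4, MRGPRX4, CTSS and FOXF1. NNMT, which methylates nicotinamide, fell 7.05-fold and 5.28-fold (adjusted p = 0.000936 and 0.00815), and GDA, guanine deaminase, 3.71-fold and 4.46-fold (adjusted p = 0.000778 and 0.00242). OAZ1, the antizyme that limits polyamine synthesis, fell 3.05-fold and 3.45-fold (adjusted p = 0.0023 and 0.00607).

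In all, 563 genes were higher and 247 lower with both constructs, 810 together and 56.6% of the genes called with construct 87, against 147.5 and 107.8 for independent lists. Both constructs were compared with the same EV libraries. At an unadjusted p under 0.05, 2083 genes were shared in the same direction, against 154 ± 13 (SD) in simulations of unchanged groups. There the EV group was simulated too, without the length trend or the pairing by replicate number, so these values may not hold for the real libraries. Fold changes of both constructs correlated with r = 0.507 across genes, which are not independent replicates, against 0.501 ± 0.0097 (SD) in the simulations. A shared control gives about this value whatever the size of the spread. The correlation alone therefore cannot tell agreement of the constructs from shared controls. The covariance of these fold changes was 0.344 against 0.0563 in the simulations (highest 0.0605), a difference of 0.288. As 3 EV libraries cannot be split between constructs, part of the excess of shared genes over independent lists may come from the shared controls. With the replicate block 2586 genes were shared. The count was 289 without EV replicate 1, 1707 without EV replicate 2, 523 without construct 86 replicate 2, 240 without construct 87 replicate 1 and 366 without construct 87 replicate 2. The test of the mean of both constructs against EV called 1810 genes higher and 1528 lower, 24.1% of those tested, and 6491 with the replicate block. Its count was 1456 without EV replicate 1, 2123 without construct 86 replicate 2 and 2209 without construct 87 replicate 1.

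**Figure D2:**
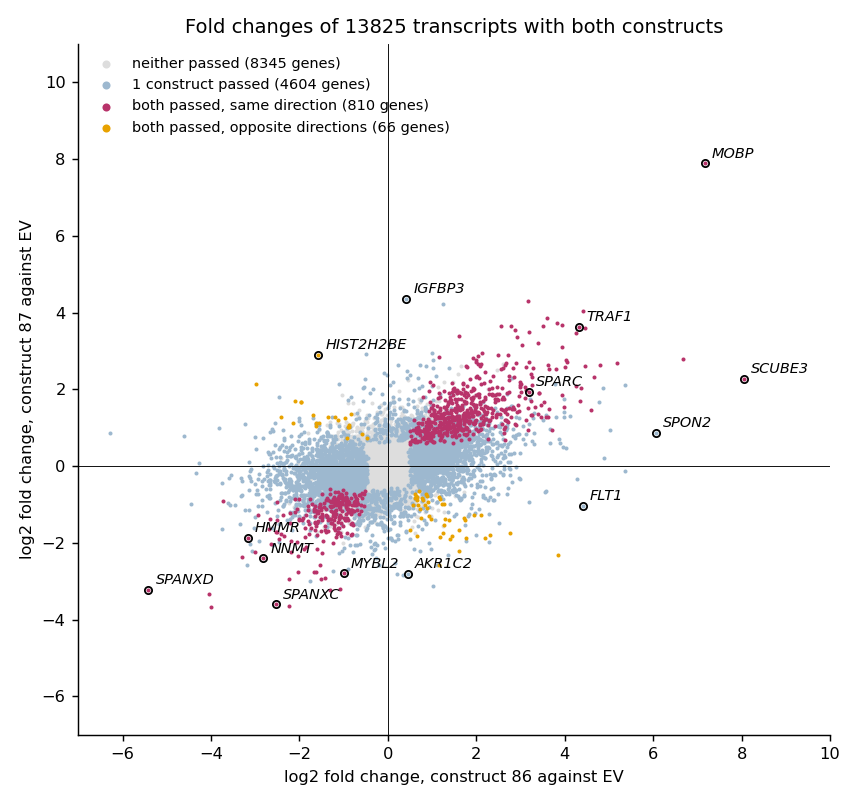
Log2 fold change against EV with construct 86 (horizontal axis) and construct 87 (vertical axis) of 13825 transcripts, 1 point each. Genes passing with both constructs are coloured by whether both changes share a direction (810) or oppose (66), and selected named genes are circled.

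The constructs were then compared with each other, since a change past the threshold with 1 construct alone is not a difference. The test of construct 87 against construct 86 called 3532 genes, 1754 higher and 1778 lower with construct 87, 25.5% of those tested, of which 1129 and 1145 differed more than 2-fold. SCUBE3 was 54.4-fold and SPON2 36.5-fold lower with construct 87 than with construct 86 (adjusted p = 3.16e-05 each), and FLT1, a receptor of VEGF, was 43.2-fold lower (adjusted p = 0.00043). IGFBP3 was 15.4-fold higher (adjusted p = 1e-04), and ALDH3B1 was 7.07-fold higher (adjusted p = 3.16e-05). Of the genes that passed with each construct, 66 changed in opposite directions, 44 of them higher with construct 86 and lower with construct 87. HIST2H2BE was 22.3-fold higher with construct 87 than with construct 86 (adjusted p = 0.000277). Of 37 lists, 12 differed between the constructs by camera. The matrix and adhesion list was lower with construct 87 than with construct 86 (adjusted p = 5.1e-05, and adjusted p = 0.48 with an estimated correlation), as were the lysosomal list (adjusted p = 0.0058, and adjusted p = 0.47 with an estimated correlation) and TGF-beta targets (adjusted p = 0.0052, and adjusted p = 0.47 with an estimated correlation). Histone genes were higher (adjusted p = 0.00085, and adjusted p = 0.47 with an estimated correlation). With the replicate block 6094 genes differed, and without construct 86 replicate 2 the count was 2216.

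**Figure D3:**
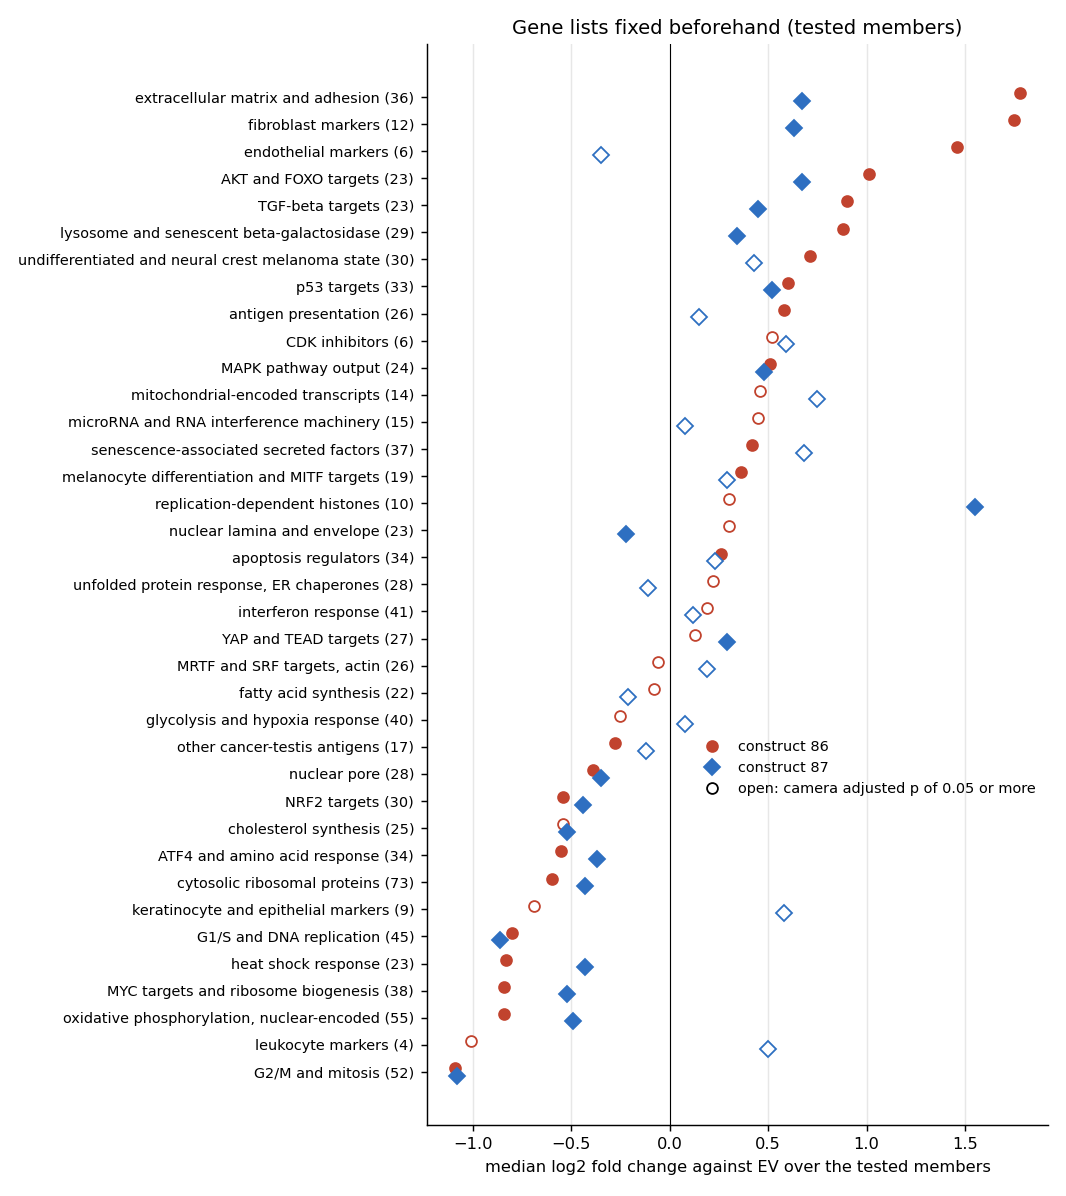
Median log2 fold change against EV (horizontal axis) of each fixed gene list with at least 3 tested members, with construct 86 as circles and construct 87 as diamonds. Filled markers have a camera adjusted p under 0.05 at the preset correlation, and the numbers in brackets are the tested members.

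Libraries also differed in how well short transcripts were represented. Relative to the mean of all libraries, the difference in log2 level between the shortest eighth of transcripts (up to 1169 nt) and the longest eighth (from 5437 nt) was 1.00, -0.56 and 0.96 in EV replicates 1 to 3, -0.29, -0.88 and -0.16 with construct 86, and -0.15, -0.44 and 0.50 with construct 87. Short transcripts of the cytosolic ribosomal proteins moved with this trend. Of 73 ribosomal protein genes 3 fell and 0 rose with construct 86 and 0 rose or fell with construct 87 (0 and 0 adjusted over the list alone for both), with median log2 fold changes of -0.60 and -0.43. Camera gave adjusted p = 0.0011 with construct 86, and adjusted p = 0.69 with an estimated correlation, and with the length trend removed the adjusted p was 0.5. With construct 87 camera gave adjusted p = 0.00059, and adjusted p = 0.69 with an estimated correlation, and with the length trend removed 0.04 (0.0063 with the replicate block as well). With the replicate block alone 43 of the 73 genes fell with construct 86 and 15 with construct 87. These calls were lost without EV replicate 3 (adjusted p = 0.0701 and 0.201), and that of construct 87 also without EV replicate 1 (adjusted p = 0.0932) and without construct 87 replicate 2 (adjusted p = 0.0843).

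**Figure D4:**
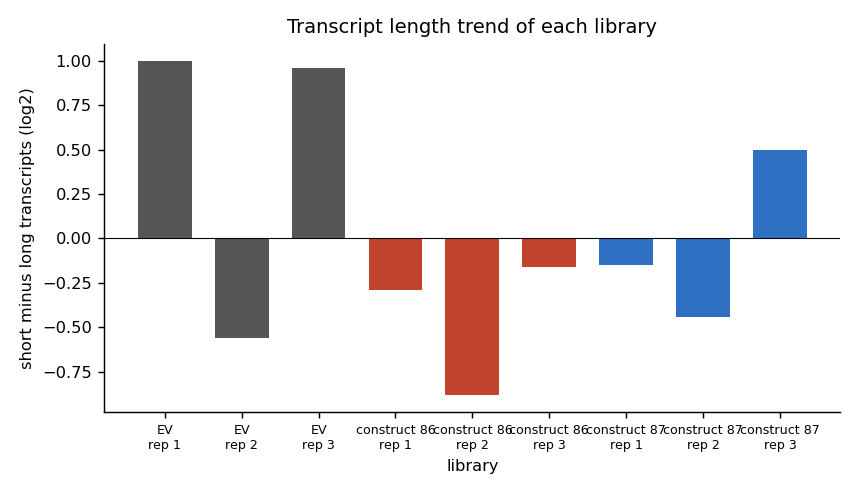
Short minus long transcripts (log2, vertical axis) in each of the 9 libraries, 1 bar per library starting at 0, coloured by group. EV replicates 1 and 3 have the highest values, 1.00 and 0.96, and construct 86 replicate 2 the lowest, -0.88.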

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

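Tests chosen only after the result was seen are the removal of the length trend from all values, the drawn splits limited to 1 library of each number per group, the mixing tests and the replicate number test on EV replicate 2, and all 3 tests on why construct 86 changed more genes.

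The comparison of both constructs stood out because 3532 genes differed between construct 87 and construct 86, where the labels give both the same target. Among them, 66 genes passed with each construct in opposite directions. Chosen after their values were seen, MMP1, an interstitial collagenase, rose 4.97-fold with construct 86 (limma adjusted p = 9.64e-05) and fell 3.46-fold with construct 87 (adjusted p = 0.0023), and TIMP3, an inhibitor of such enzymes, rose 2.73-fold and fell 3.55-fold (adjusted p = 0.00494 and 0.0065). CALB2, which encodes calretinin, fell 2.55-fold with construct 86 and rose 2.42-fold with construct 87 (adjusted p = 0.00242 and 0.0114).

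By camera, 12 gene lists differed between the constructs. Lists lower with construct 87 than with construct 86 were extracellular matrix and adhesion (adjusted p = 5.1e-05, and adjusted p = 0.48 with an estimated correlation), TGF-beta targets (0.0052), lysosome (0.0058), antigen presentation, the unfolded protein response and endothelial markers (adjusted p = 0.044 each), all 5 of the latter with adjusted p = 0.47 with an estimated correlation. The nuclear lamina and envelope list was also lower (adjusted p = 0.044, and adjusted p = 0.86 with an estimated correlation). Lists higher with construct 87 than with construct 86 were the replication-dependent histones (0.00085) and leukocyte markers (0.044, on 4 tested genes), each with adjusted p = 0.47 with an estimated correlation. The MYC and ribosome biogenesis list and the heat shock list were also higher (0.036 each, and adjusted p = 0.86 with an estimated correlation), as was oxidative phosphorylation (0.038, and adjusted p = 0.96 with an estimated correlation). With the length trend removed, 3 of these 12 differences no longer passed: oxidative phosphorylation (0.21), the nuclear lamina and envelope (0.062) and leukocyte markers (0.11).

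Outside the tested genes, some transcripts stood at 0 throughout the construct 87 libraries or throughout the EV and construct 86 libraries. Filtering appears to have been done separately. Of 400 genes at 0 with construct 87, 264 were higher with construct 86 than in EV libraries and 0 lower by limma, 166 of them more than 4-fold. The filter itself favours such genes, since none of the 400 reached 14 in all 3 EV libraries. SLC45A2, a melanosomal transporter, went from 2.06 ± 1.08 to 181 ± 76.2 (SD, n = 3 each) and MMP12, an elastase, from 2.50 ± 1.79 to 87.7 ± 51.4, both chosen after their values were seen. Of 453 genes at 0 in EV and construct 86 libraries, 189 had values of 14 or more in all 3 construct 87 libraries, such as KLHL3, chosen after its values were seen, at 67.1 ± 7.88.

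Other splits of the libraries were fitted in the same way. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Among them the real split of construct 86 and EV gave 4925 genes and 23 lists against 0 genes by limma (2160 at an unadjusted p under 0.05) and 20 lists at most in any other, so 1 split of 10 was as large for each. For construct 87 the real split gave 1431 genes and 20 lists against 1171 and 19 at most, again 1 of 10 for each. Every other split called lists too, at least 8 for construct 86 and at least 7 for construct 87. List calls at the preset correlation therefore arose whatever the grouping, and their number does not by itself show an effect of a construct. For construct 87 against construct 86 the gene counts were 3532 and 0 (605 at an unadjusted p under 0.05), also 1 of 10. The split with 1171 genes exchanged EV replicate 2 with construct 87 replicate 3, which follows the transcript length trend; with that trend removed it gave 0 genes (2772 at an unadjusted p under 0.05) while the real split gave 2179. Since the numbers pair the libraries, the 4 of 10 splits with 1 library of each number per side come closest to the real ones. The highest others among these gave 0 genes for each of the 3 comparisons (82, 90 and 103 at an unadjusted p under 0.05). Every split other than the real one has libraries of both groups on each side. A real difference between the groups then widens the spread within sides and lowers the count. Low counts there are partly fixed in advance and cannot show what chance alone would give.

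With all knockdown libraries as 1 group against EV, 1018 genes passed, and 3 of 84 splits gave as many. Because the replicate numbers pair the libraries, these splits are not interchangeable, so that share cannot exclude chance. Of the 27 splits with 1 library of each number in the smaller group, which compare best with the real one, 2 gave as many, so that among these chance cannot be excluded. The highest other, with 3579 genes, set the 3 construct 86 libraries against the rest, several times the real count, which points to a structure of the libraries in which construct 86 stands apart. The other, with 1727, set EV replicates 1 and 3 and construct 87 replicate 3 against the rest; with the length trend removed it gave 0 (3228 at an unadjusted p under 0.05) and the real split 1386. For the 810 genes shared by both constructs, 2 of 100 drawn splits gave as many (highest other 1849). These splits ignore the replicate numbers, so they cannot exclude chance either. Of 100 drawn splits with 1 library of each number in every group, 5 gave as many (highest other 2384), so that among these chance cannot be excluded; the 4 others all set the construct 86 libraries in the place of EV. For the correlation of 0.507, 58 of the 100 splits that ignore the numbers gave as high a value (highest other 0.923). Every split compares 2 groups with 1 shared group, which by itself raises the correlation, so this test cannot decide about chance.

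Ribosomal protein and oxidative phosphorylation transcripts, both short, were lower with construct 86, with medians of -0.60 (SD 0.36) and -0.84 (SD 0.40). Set against genes of matched length, the oxidative phosphorylation list was lower by a median difference of -0.41 (bootstrap interval -0.48 to -0.30). The intervals given here resample genes, not libraries, so they do not measure the spread between libraries. With the length trend removed its median was -0.39 (SD 0.45) and its camera adjusted p 0.0019. This argues against the recovery of short transcripts as its whole cause. With the trend kept, its fry adjusted p was 0.086. A fall of this list, which is nuclear-encoded, with knockdown beyond the length trend may remain. Mitochondrial-encoded transcripts went the other way with construct 86, with a median of 0.46. Their camera adjusted p was 0.28, upward, then 0.04 with the length trend removed and 0.79 with an estimated correlation. The ribosomal list differed from its matched genes by a median of -0.14 (-0.23 to -0.04), and its median went to -0.18 (SD 0.34) with the trend removed, so recovery by length could account for most of it. Its camera adjusted p was then 0.5, while with construct 87 the difference from matched genes was -0.14 (-0.24 to -0.09) and the camera adjusted p 0.04, so whether knockdown moved it beyond length stays open.

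EV replicate 2 lay towards the knockdown libraries, its shift following the construct 86 contrast with a slope of 0.374 and the construct 87 contrast with 0.534. The other EV libraries stand on both sides of this fit, which by itself raises the slope. With nothing mixed in, EV replicates 1 and 3 set against each other gave slopes of 0.0847 and 0.149 for construct 86. For construct 87 they gave 0.143 and 0.281. Part of the slope may therefore be built in and not belong to EV replicate 2. Construct 86 RNA or reads mixed into it are argued against as the whole cause, because construct 86 values mixed in silico into the other EV libraries gave this slope at shares of 0.198 to 0.312, while MMP9, SCUBE3 and ACAN, on average under 1% of their construct 86 level in the other EV libraries, stood at shares of 0.0144, 0.00198 and 0.0198 (0.0414, 0.0247 and 0.0304 would put each gene itself on the slope). Mixing of construct 87 RNA is argued against as the whole cause too, since it needed shares of 0.309 to 0.505, while over 7 abundant genes at least 10-fold above the other EV libraries the median share was 0.0239 (-0.0273 to 0.14). The length trend carries part of the shift, as 61.3% of the slope remained with the trend removed for construct 86 and 63.2% for construct 87. A difference carried by the replicate number 2, such as a shared day or batch, may contribute, though the labels give no batch and no biological explanation was tested. The deviations of EV replicate 2 correlated across genes with those of replicate 2 of construct 86 (r = 0.74) and construct 87 (r = 0.78). These correlations were computed with the length trend in place. Replicate 2 had the lowest short minus long value of each group (-0.56 for EV, -0.88 with construct 86, -0.44 with construct 87). The length trend and the replicate number were therefore not told apart here. The targeted transcripts were also lowest in EV replicate 2 among the EV libraries. SPANXC stood at 149.8 there, against 400 and 510.9 in EV replicates 1 and 3, and SPANXD at 27.4 against 102.2 and 97.01. Whether this bears on the shift was not tested.

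Construct 86 changed 3.44 times as many genes as construct 87. This ratio was 12.2 without construct 87 replicate 1, 7.29 without construct 87 replicate 2 and 6.63 without EV replicate 1. It was 2.36 without EV replicate 2, 2.88 without construct 86 replicate 2 and 2.93 without construct 86 replicate 1. A larger spread between construct 87 libraries is argued against, because the median SD was 0.245 with construct 86 and 0.253 with construct 87. With the replicate block construct 86 still gave 1.79 times as many. That ratio cannot decide this, since the fit pools the spread of all groups and gives both constructs the same standard error. The length correction gave 5421 genes with construct 86 and 2179 with construct 87, and with the replicate block as well 7673 and 4845. Separate filtering and scaling of the construct 87 files is also argued against as the whole cause, since with a stricter filter and under 3 other scalings the lowest ratio was 3.26. A deeper knockdown by construct 86 could be a candidate explanation, and this stays open. SPANXC was at a mean 2.33 times as high with construct 86 as with construct 87, while SPANXD was lower with construct 86. The sum of both genes was 7.12-fold lower than in EV libraries with construct 86 and 13.5-fold lower with construct 87. In sum the mean knockdown was thus not deeper with construct 86, though single libraries overlapped (102.7, 36.01 and 42.21 against 30.48, 23.98 and 40.73). The SPANXC mean rests largely on construct 86 replicate 1 (101.7, against 35.14 and 42.21 in replicates 2 and 3). The SPANXC difference did not pass (limma adjusted p = 0.149, and 0.0221 with the replicate block). Effects of a construct on other transcripts were not tested.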

How the results depend on the processing

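Tests chosen only after the data were seen are the values as deposited, pseudocounts of 0.5 and 8, no variance trend, and the length correction, alone or with the replicate block. Counts are of genes with construct 86, with construct 87, for the mean of both, shared by both and differing between them (main values 4925, 1431, 3338, 810 and 3532). The replicate block gave 7647, 4284, 6491, 2586 and 6094, and with the length correction 7673, 4845, 6602, 2784 and 6608. The length correction alone gave 2179 with construct 87. Fitting only the groups compared gave 858 with construct 87 and 493 shared, with fewer libraries to estimate the spread. Requiring a fold change over 2 as well gave 3160 with construct 86, 1607 for the mean, 530 shared and 2274 differing. Where not given by construction, the cause was not tested. Leaving out 1 library at a time gave 3075 to 6035 with construct 86, 378 to 2556 with construct 87, 1456 to 4761 for the mean, 240 to 1707 shared, 2216 to 4210 differing, and a correlation of 0.464 to 0.611. All other counts under voom, RLE, total reads, a stricter filter, deposited values, other pseudocounts and no variance trend stayed within 1.5 times the main count. Lists past the threshold went from 23 and 20 to 0 and 0 with an estimated correlation in camera (5 and 4 at an unadjusted p under 0.05), with fry 24 and 16. No named gene or list that passed changed direction, but the balance of calls turned with the length correction, to 2551 higher and 2870 lower with construct 86, 1073 and 1106 with construct 87, 1888 and 2055 for the mean and 2193 and 2079 for the difference (with the replicate block added, 3533 and 4140, 2350 and 2495, 3024 and 3578, and 3414 and 3194). It also turned with the replicate block, to 3731 and 3916 with construct 86, 3216 and 3275 for the mean and 3073 and 3021 for the difference, and among differing genes the share higher with construct 87 (main 49.7%) went to 54.7% with total reads, 50.2% without a variance trend and 51.9% with deposited values, which also took the share higher with construct 86 from 50.6% to 49.3%. Of 281 calls of named genes, 201 held under every setting and 80 were lost in at least 1, most without EV replicate 1 (63) or construct 87 replicate 1 (56). The replicate block lost 0 of them and gained 50. DESeq2 was not run, as the values are scaled and rounded, nor a fit without a filter, as the authors had filtered. Low depth limits genes near 0, such as SPANXD with construct 86.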

Other observations

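Tests chosen only after the result was seen are those on NF-kB targets and on SLBP.

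Several gene groups not described above also moved with construct 86. Antigen presentation genes rose in 10 of 26 tested members and fell in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0081, and adjusted p = 0.36 with an estimated correlation), with HLA-B, a class I heavy chain with close copies, up 2.57-fold (limma adjusted p = 0.000778). With construct 87 HLA-B rose 3.07-fold (adjusted p = 0.00223) while 3 of the 26 rose and 0 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.33). Genes of the undifferentiated and neural crest melanoma state rose in 14 of 30 and fell in 5 (14 and 6 adjusted over the list alone; camera adjusted p = 0.029, and adjusted p = 0.49 with an estimated correlation), among them NT5E, the ecto-enzyme CD73, 8.54-fold (adjusted p = 7.6e-05). Outputs of the MAPK pathway rose in 10 of 24 and fell in 3 with construct 86 (12 and 3 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.53 with an estimated correlation), and rose in 6 and fell in 1 with construct 87 (9 and 2 adjusted over the list alone; camera adjusted p = 0.002, and adjusted p = 0.49 with an estimated correlation). DUSP5, a phosphatase of ERK, rose 4.95-fold and 4.67-fold (adjusted p = 7.11e-05 and 0.000481), and SPRY2, a feedback inhibitor of this pathway, 2.47-fold and 2.4-fold (adjusted p = 0.00133 and 0.0065). Of 6 endothelial markers 4 rose and 0 fell with construct 86 (4 and 0 adjusted over the list alone; camera adjusted p = 0.029, 0.0635 with a stricter filter, and adjusted p = 0.32 with an estimated correlation), FLT1 21.2-fold among them (adjusted p = 0.00086); with construct 87 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.91).

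Further lists passed with construct 87. Cholesterol synthesis genes fell in 5 of 25 and rose in 0 (11 and 1 adjusted over the list alone; camera adjusted p = 6.9e-05, and adjusted p = 0.32 with an estimated correlation), with INSIG1, a sterol sensor of the endoplasmic reticulum, 3.32-fold lower (adjusted p = 0.00804). NRF2 targets fell in 4 of 30 and rose in 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00064, and adjusted p = 0.4 with an estimated correlation), such as CBR3, a carbonyl reductase, 3.63-fold (adjusted p = 0.00509). Genes of the ATF4 and amino acid response fell in 6 of 34 and rose in 3 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.51 with an estimated correlation). SCD, a fatty acid desaturase, fell 2.49-fold with construct 86 and 2.59-fold with construct 87 (adjusted p = 0.000702 and 0.00299). Heat shock genes fell in 2 of 23 and rose in 0 with construct 87 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00093, and adjusted p = 0.49 with an estimated correlation). Every list call with either construct that is not given here or in the text above ended when some single library was left out. Among lists that did not pass, the camera adjusted p was 0.26 and 0.22 for CDK inhibitors, 0.087 and 0.17 for the interferon response, and 0.69 and 0.23 for glycolysis and hypoxia with construct 86 and construct 87. The median and the mean log2 fold change differed in sign for 4 uncalled lists: with construct 86 the MRTF and SRF targets (-0.06 and 0.04), the histones (0.30 and -0.13) and keratinocyte markers (-0.69 and 0.05), and with construct 87 the endothelial markers (-0.35 and 0.14).

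A hypothesis concerns NF-kB, a transcription factor of inflammatory genes, because BIRC3, TRAF1 and TNFRSF9, all targets of it, were among the 12 largest rises shared by both constructs. With construct 87 the call of BIRC3 (adjusted p = 0.0123) was lost without EV replicate 1 (adjusted p = 0.0673) and without construct 87 replicate 1 (adjusted p = 0.0521), and that of TNFRSF9 (adjusted p = 0.0105) without construct 87 replicate 1 (adjusted p = 0.0501). The rises with construct 86 were uneven and smallest in replicate 1. BIRC3 stood at 333.2, 3120 and 4568 in construct 86 replicates 1 to 3. TNFRSF9 stood at 36.8, 268.8 and 323.6, and TRAF1 at 709, 1747 and 1683. A list of 40 other NF-kB targets was then drawn up, of which 35 were tested and 11 also stand in the fixed lists. With construct 86, 14 rose and 1 fell, with a median log2 fold change of 0.61 (camera adjusted p = 0.001), and with construct 87 8 rose and 0 fell, with a median of 0.50 (camera adjusted p = 0.017). Both were adjusted p = 0.43 with an estimated correlation. The camera p-values of this list were adjusted over both constructs alone, not over the fixed lists, so they are less strictly adjusted than those of the fixed lists. CD83, a surface protein of activated immune cells, rose 4.75-fold and 2.64-fold (limma adjusted p = 0.000144 and 0.0065), while SDC4, a syndecan, rose 6.21-fold with construct 87 (adjusted p = 0.00105), more than with construct 86 (adjusted p = 0.000992 for the difference); both were chosen after their values were seen. Other members rose with construct 86 only. CD44 and CSF1 rose 2.63-fold and 4.01-fold there (limma adjusted p = 0.00128 and 0.00306). With construct 87 they were 4.15-fold and 5.87-fold lower than with construct 86 (adjusted p = 0.000287 and 0.00119). At the preset correlation, other splits of the libraries called up to 20 and 19 fixed lists, against 23 and 20. A rise of NF-kB targets at large may accompany both constructs, but these calls do not establish it. The pattern was found and tested on the same libraries.

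A further hypothesis was that the higher replication-dependent histone transcripts with construct 87 follow a lower level of SLBP, which binds the stem-loop at the end of histone mRNAs, since histone mRNAs that escape this processing are polyadenylated and 3' end counting then detects them. SLBP fell with construct 86 from 1882 ± 357 to 1123 ± 154 (SD, n = 3 each; limma adjusted p = 0.0216) and with construct 87 to 999 ± 198 (adjusted p = 0.0239), with no difference called between the constructs (adjusted p = 0.592). Histones were not called as a list with construct 86 (camera adjusted p = 0.93; 3 rose and 3 fell of 10, and 3 and 3 adjusted over the list alone) and differed between the constructs (adjusted p = 0.00085). A fall of SLBP with both constructs argues against its level as the whole cause.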
